A study of Arabidopsis thaliana with 6 samples.

How the data were processed

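RNA was measured in 6 samples of Arabidopsis thaliana seedlings of the Columbia accession (Col-0), 3 from wild type plants and 3 from plants mutant for SET DOMAIN GROUP 2 (sdg2). Per the labels' protocols, whole seedlings were raised on plates of diluted Murashige and Skoog medium for 10 days at 22 °C with light for 24 h per day, total RNA was taken with Trizol and cleaned on RNeasy columns, and biotin-labelled RNA was made with the Affymetrix 3' IVT Express kit. The sample titles call the 3 samples of each genotype biological replicates. Nothing in the labels says how they were separated into cultures or plates, so p-values measure only the spread between these samples, which may be partly technical.

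The values analysed are the authors' processed table with 1 column per array. They are on the log2 scale, and GCRMA, which combines background adjustment, quantile normalization and summary of probes into probe sets, is the processing named per the submitters' processing notes. Its version and settings are not given in the sources used here. GCRMA values carry no call of presence or absence. Values of unexpressed probe sets pile up at a lower mode, which lay between 2.18 and 2.21 on the 6 arrays, and a fold change against such a value is not a measured ratio of amounts.

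The table holds 22810 probe sets. The 64 Affymetrix control probe sets were left out of the tests and looked at separately, which left 22746. Of these, 13513 name 1 gene in the platform annotation supplied, 503 name several and 8730 are not listed there and stay unnamed here. No gene was named from a probe set with several. Symbols were updated through the NCBI gene table of assembly TAIR10.1, which matched 13436 of the probe sets naming 1 gene, and 13286 genes remained when each was represented by its brightest probe set over the 6 arrays. The assembly was used only for names and for the order of genes. SDG2 itself, FLC and the other H3K4 methyltransferase genes of the lists have no probe set named in these tables and were not analysed here, so the labels could not be checked against the mutated gene.

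Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means only), sdg2 minus wild type, with Benjamini-Hochberg adjustment over all 22746 probe sets. A probe set was called changed at an adjusted p below 0.05, and counted again at a change of at least 2-fold. Errors of log2 changes are the moderated standard errors of this fit. Values were also simulated with the means and spreads of these arrays, with independent errors and with 100 probe sets changed at each size. The fit recovered 72 of 100 changed by 1 log2 unit and 42 of 100 changed by 0.5. It made 3 false calls among the probe sets left unchanged. Far fewer probe sets were changed there than the 8327 called in the real comparison, so these rates do not carry over to it.

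Gene lists were tested with camera at its preset inter-gene correlation of 0.01 against all other genes, for lists with at least 3 measured members, and beside it with camera at an estimated correlation and with fry. The design, the tests, the 22 fixed lists with 351 members, the alternatives for them and the rule for the genes named were chosen before the data were examined. Only 46 of the 351 members have a named probe set, 4 lists have none and 10 could be tested. A further 20 lists with 515 measured genes were therefore drawn up from the probe annotation by gene symbol, locus or chromosome, before any value was compared between the groups, and are called added lists here. A planned list of ribosomal proteins by gene description was replaced by an added list by locus, because the gene table used here has no descriptions.

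The rule for named genes took the 12 largest rises and the 12 largest falls among changed probe sets that name 1 gene, whose groups do not overlap and whose brighter group has a mean of at least 6, and of each list up to 2 members with the largest rise and 2 with the largest fall past the threshold, or the member with the largest absolute change where none passed. SDG2, FLC and the H3K4 methyltransferases were also in the rule. The part on lists was applied to the added lists as well. Where a fixed list has few measured members the text names all of them, and those outside the rule were thus chosen after their values were seen; other genes outside the rule are marked where they appear. Figures were drawn with matplotlib 3.10.9.

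The alternatives were a replicate block, quantile normalization, median centring, a filter keeping probe sets at a log2 value of at least 5 on at least 3 arrays, eBayes with trend and robust, array weights, unmoderated statistics, only probe sets naming 1 gene, limma's treat with a minimum change of 0.5, the mean of a gene's probe sets and leaving out each array in turn. The 3' minus 5' signal of the control probe sets was compared with an exact permutation test. Replicate numbers are shared between the groups, but the labels do not say that a number marks a common batch. The number of arrays, 3 per group, limits the precision of every comparison.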

Results

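Gene expression was profiled in 10-day-old Arabidopsis seedlings on 1-colour Affymetrix arrays, with 3 arrays of wild type and 3 of the sdg2 mutant. SDG2 is a SET domain protein that trimethylates lysine 4 of histone H3 (H3K4), a mark found at active genes. The median log2 value was between 5.90 and 5.96 on the 6 arrays, and 56.8% to 57.1% of the 22746 probe sets lay at 5 or above. Arrays of the same genotype correlated at 0.997 to 0.998 over all probe sets and arrays of different genotype at 0.970 to 0.971. No more than 8 probe sets had identical values on any pair of arrays.

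The comparison of sdg2 with wild type asks which transcripts differ in seedlings mutant for this methyltransferase. DFR, which encodes the dihydroflavonol reductase of anthocyanin synthesis, rose by 5.09 ± 0.12 (SE, n = 3 per group) on the log2 scale, the largest rise under the rule for named genes. AT1G66100, a gene of the thionin family, fell by 6.08 ± 0.13, a 67.5-fold difference and the largest fall. Cold-regulated COR15A rose by 3.90 and the plant defensin PDF1.2 by 3.79. Genes for cytosolic ribosomal proteins fell together by a small amount, with a median of -0.38. Of the 22746 probe sets, 8327 (36.6%) changed at an adjusted p below 0.05 in limma, 4327 of them higher and 4000 lower in sdg2. At 2-fold or more, 2406 changed, 1152 higher and 1254 lower, and 1197 of these name 1 gene (522 higher, 675 lower). A change of at least 10-fold was found for 133 probe sets, 78 higher and 55 lower. The wild type mean was below 3 in 27 of these 78 and the sdg2 mean in 8 of the 55, so those folds are not measured ratios. In 48.3% of all probe sets the values of the groups did not overlap, against 10% by chance for 3 arrays against 3. The median change over all probe sets was -0.01. The quantile normalization in GCRMA gives all arrays much the same distribution, so this median and the balance of higher and lower calls cannot show a global shift. The 3' minus 5' signal of the actin, GAPDH and ubiquitin controls, a sign of RNA integrity, differed by 0.03 between the groups on average (exact permutation test, two-sided p = 0.7, where 3 against 3 cannot go below 0.1). The average covers differences of -0.06 for actin, -0.01 for GAPDH and 0.18 for ubiquitin, whose groups did not overlap (exact two-sided p = 0.1).

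Among the 12 largest rises, DFR went from 2.29 ± 0.22 (SD, n = 3) in wild type to 7.38 ± 0.07 in sdg2 (adjusted p = 1.62e-05). The wild type value lies at the level of unexpressed probe sets, so the 34.0-fold difference is not a measured ratio of amounts. CHI at locus AT2G43570, a chitinase gene and not the chalcone isomerase of the same abbreviation, rose 25.5-fold and AT1G26380, an FAD-linked oxidoreductase gene of pathogen responses, 23.8-fold. The receptor kinase gene AT1G35710 rose 15.1-fold and the carnitine transporter gene OCT1 15.7-fold. The wild type means of AT1G26380, AT1G35710 and OCT1 were below 3, close to background. COR15A rose 14.9-fold, from 6.02 to 9.92, and AT2G16660, a gene of the major facilitator family, 18.0-fold, from 6.09 to 10.26. AT3G28500, which encodes an acidic ribosomal P2 protein, rose 14.6-fold. AT1G12030, AT1G19200 and AT3G26460 rose by 4.14, 4.09 and 3.93, and AT5G52760 by 3.86 ± 0.41, the largest error of the group.

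Among the 12 largest falls, 9 had a wild type mean above 8. AT1G66100 went from 11.72 to 5.65 (adjusted p = 1.33e-05). AT3G62950, a glutaredoxin gene, fell 55.7-fold and reached 2.40 in sdg2, the level of unexpressed probe sets. AT1G19530 fell 47.1-fold with an SE of 0.05 on its log2 change of -5.56. Lipid-transfer-type genes AT1G62510 and AT5G48490 fell 22.3-fold and 16.4-fold. The glycine-rich protein gene AT2G05540 fell 15.9-fold from the highest wild type mean of the group, 13.34. AT4G33666, AT4G39675, AT3G29970, AT5G35940, AT1G21500 and AT1G13650 fell between 13.7-fold and 21.9-fold, and the sdg2 means of AT3G29970 and AT1G13650 were below 3. AT5G35940 encodes a jacalin-type lectin.

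**Figure D1:**
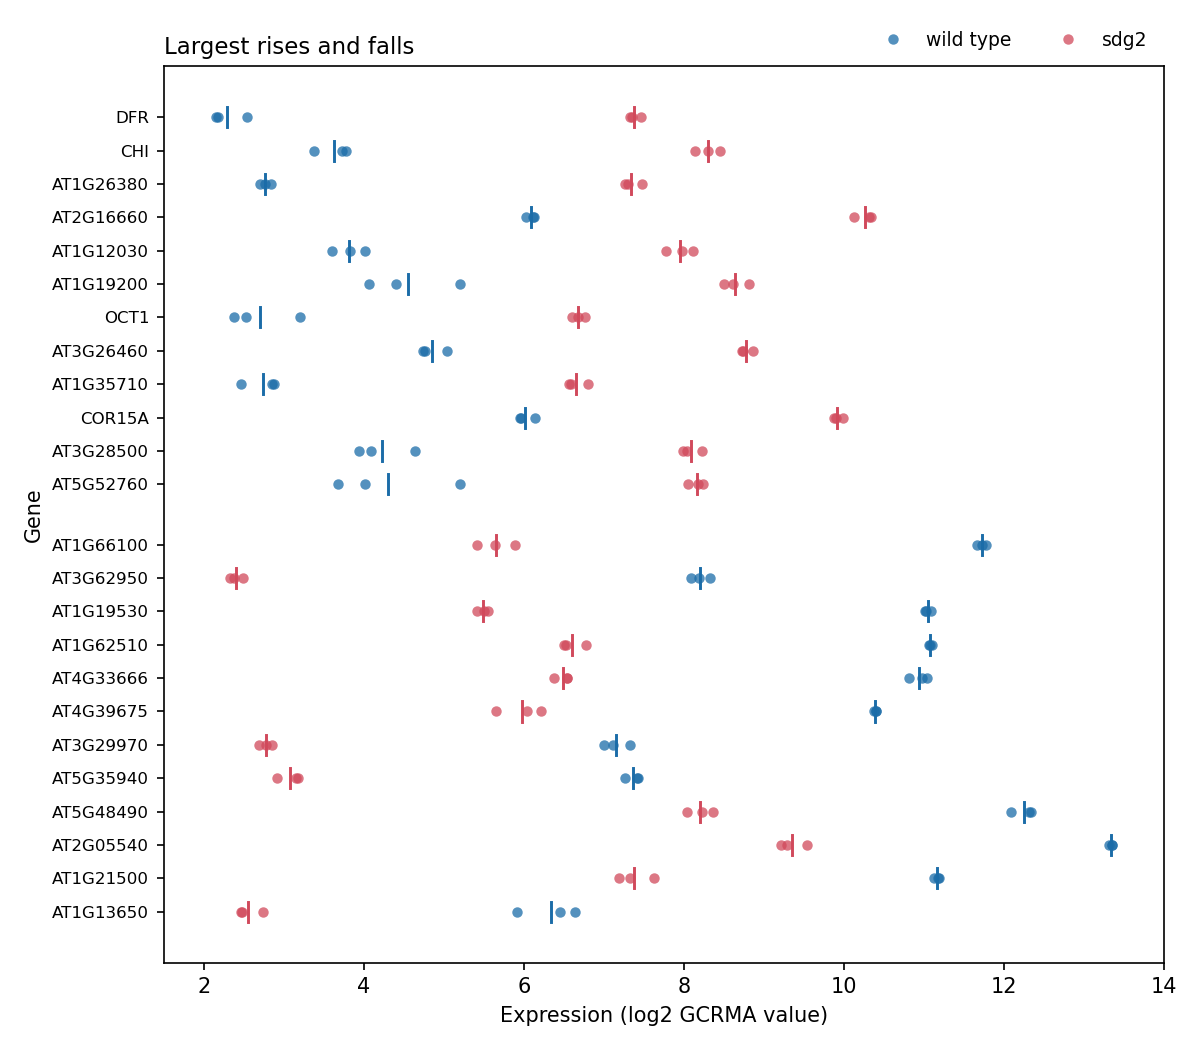
Log2 GCRMA values of the 12 genes with the largest rise and the 12 with the largest fall in sdg2 (horizontal axis, 1 row per gene), with a point for each of the 3 wild type and 3 sdg2 arrays and a vertical bar at each group mean. The groups do not overlap for any of these genes, and DFR in wild type, with a mean of 2.29, and AT3G62950 in sdg2, with a mean of 2.40, sit near the lower end of the scale.

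Genes of flavonoid and anthocyanin synthesis rose in all 3 of the 16 listed members that were measured. Beside DFR, the anthocyanin glucosyltransferase gene AT4G14090 (UGT75C1) rose by 3.31 ± 0.34 and the anthocyanin glycosyltransferase gene UF3GT by 2.70 ± 0.09, from wild type means of 3.00 and 2.14, near background. Camera called this list higher at an adjusted p = 0.00141, a call lost at adjusted p = 0.199 with an estimated correlation. The senescence list also had 3 measured members, all higher. WRKY6 rose by 1.09 and WRKY53 by 0.38, both transcription factors active in ageing leaves, and SAG29 by 0.37 from 2.07, a value at background. Camera called it higher at an adjusted p = 0.00697, a call lost at adjusted p = 0.361 with an estimated correlation. With the filter on dim probe sets, each of these lists kept 2 members and could not be tested.

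The 1 measured gene each of the jasmonate and salicylic acid lists rose, and the auxin response list moved in both directions. PDF1.2, a jasmonate- and ethylene-responsive defensin, rose 13.8-fold (3.79 ± 0.20) and was the only measured member of the jasmonate list. SAG101, a partner of EDS1 in immune signalling, rose by 1.75 ± 0.16 and was the only measured member of the salicylic acid list. In the auxin response list GH3.3 rose by 1.74 ± 0.04 while WES1 (GH3.5), a relative that also conjugates auxin to amino acids, fell by 1.16 ± 0.06. The other member, IAA29, had a change of -0.70 that did not pass over all probe sets and passed when adjusted over the list alone (3 passed adjusted over the list alone, 2 over all). The median of the list was -0.70 and its mean -0.04, and camera gave the direction down (adjusted p = 0.910) where fry gave up.

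All 4 measured members of the cold, drought and ABA list changed, in opposite directions. COR15A and COR15B, similar genes for chloroplast-protective proteins whose probe sets were not tested for reading each other's transcripts, rose by 3.90 and 3.64, whereas the dehydrin genes LTI30 and COR47 fell by 1.79 and 1.13. Camera did not call the list (adjusted p = 0.910; adjusted p = 0.922 with an estimated correlation). BHLH101, an iron-deficiency transcription factor and the only measured member of the iron and phosphate list, rose by 3.55 ± 0.10 from a wild type mean of 2.98.

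Of the H3K4 methylation machinery, 7 of 26 listed genes were measured, none of them a methyltransferase, and 1 rose, 3 fell and 3 did not pass. RBL, a core subunit of H3K4 methyltransferase complexes, rose 2.47-fold, from 4.91 to 6.21. ULT1, a trithorax-type factor, fell by 0.72 ± 0.08, the demethylase gene PKDM7D (JMJ16) by 0.48 ± 0.08 and the WD40 gene AT5G66240 (S2LB) by 0.44 ± 0.07. AT5G14530 (S2LA), AT1G63490 (JMJ17) and LDL2 had changes of -0.48, 0.75 and 0.00 that did not pass. The count was 6 adjusted over the list alone, and camera did not call the list (adjusted p = 0.826). DME, a DNA demethylase gene, rose by 0.86 ± 0.14 on its brightest probe set, while its other, dimmer probe sets had values of -0.02 and 0.21 that did not pass.

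None of the 5 measured flowering-time genes passed in limma, 0 had an unadjusted p below 0.05 and 0 passed with unmoderated statistics. The largest change was that of SMZ, 0.61 ± 0.25 (adjusted p = 0.131), and FD and AGL19 lay below 3 in both groups. In the list of shoot meristem and leaf polarity genes PHV rose by 0.93 ± 0.10 and YAB3 fell by 0.30 ± 0.07, both leaf polarity regulators, and CLV3 was at background with 2.05 in both groups. The call for YAB3 was lost, among other settings, without sdg2 replicate 1 (adjusted p = 0.0631) or sdg2 replicate 2 (adjusted p = 0.0625). The median of that list was -0.01, its mean 0.21 and its camera direction up (adjusted p = 0.910).

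Of 19 listed nuclear photosynthesis genes 3 were measured. LHCB4.2, a light-harvesting antenna gene, fell by 0.77 ± 0.06, while LHCB4.1 and RCA, with changes of 0.08 and 0.09, did not pass. LHCB4.3, a relative outside the list chosen after its values were seen, rose by 3.25 ± 0.21, from 6.15 to 9.40. The median of the list was 0.08, its mean -0.20 and its camera direction down (adjusted p = 0.910). Root tissue markers, included as a gauge of tissue make-up, fell in 2 of 3 measured genes. EXPA18 and PYK10 each fell by 0.33, and EXPA7 had a change of -0.75 that did not pass. The call for PYK10 was lost, among other settings, with quantile normalization (adjusted p = 0.126) and without wild type replicate 2 or 3 or sdg2 replicate 1 or 3 (adjusted p of 0.109 to 0.122). Camera did not call the list (adjusted p = 0.292).

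Other fixed lists with any measured member, apart from the reference genes below, had 1 or 2 and were not tested as lists. PRL (MCM7), a replication licensing gene, rose by 1.00 ± 0.15, and UGT74B1, of glucosinolate synthesis, by 0.76 ± 0.06. BCAT4, the other measured glucosinolate gene, had a change of -0.12 that did not pass. The clock gene GI rose by 0.40 ± 0.12 (adjusted p = 0.0469), a call lost with quantile normalization (adjusted p = 0.0764), with median centring (0.0677), with unmoderated statistics (0.0975), with only probe sets naming 1 gene (0.0562) and when any array but sdg2 replicate 3 was left out (0.0577 to 0.135). The heat shock gene ATHSP22.0 was at background in both groups, 2.27 and 2.25. Genes commonly used as references for normalization also changed, all 3 that were measured. Camera did not call their list (adjusted p = 0.910, or 0.922 with an estimated correlation). PEX4 (UBC21) fell by 0.37, AT4G34270 (TIP41) fell by 0.30 and AT2G28390 (SAND) rose by 0.25. The call for AT4G34270 was lost, among other settings, without wild type replicate 1 or 3 or sdg2 replicate 1 or 2 (adjusted p of 0.0514 to 0.0957). The Polycomb, floral homeotic, root meristem and seed maturation lists had no measured member. For every fixed list not given a second count here, the number passing was the same adjusted over the list alone.

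Among the added lists, the genes of cytosolic ribosomal proteins stood out by number. Of 72 measured on the list, 54 fell, 1 rose and 17 did not pass, and 58 passed adjusted over the list alone. AT3G28500, the P2 protein gene that rose 14.6-fold, is not on the list and not in these counts. Changes within the list were small, with no member at 2-fold, a median of -0.38 and extremes of -0.96 in AT1G15250 and 0.27 in AT4G34555. AT3G28900 fell by 0.93 ± 0.06. The rise of AT4G34555 lost its call, among other settings, with median centring (adjusted p = 0.0722) and without any array but wild type replicate 3 (0.0826 to 0.123). Camera called the list lower at an adjusted p = 2.01e-12 and at an adjusted p = 0.0170 with an estimated correlation. Camera at its preset correlation also called the list in 7 of the other 9 ways to split the 6 arrays into 3 and 3, with medians of at most 0.14 in size, and each of these splits mixes the genotypes unequally and so keeps part of their difference.

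Of 18 measured genes of expansins, known for loosening cell walls, and of expansin-like proteins such as EXLA3, 8 fell and 1 rose. EXLA3 fell by 2.45 ± 0.10, EXPA8 by 2.04 ± 0.07, and EXPA15 rose by 0.53 ± 0.06. Camera called the list lower (adjusted p = 0.0215; adjusted p = 0.257 with an estimated correlation), and the call was lost with array weights (adjusted p = 0.0781) and with the filter on dim probe sets (0.0676), which left 13 members and moved the median from -0.24 to -0.75. Of 13 measured OTP and CRR genes, which encode pentatricopeptide repeat and related proteins of organelle RNA processing, 4 rose and 9 did not pass. OTP84 rose by 1.34 ± 0.08 and OTP81 by 1.18 ± 0.14. Camera called this list higher (adjusted p = 0.0130, or adjusted p = 0.257 with an estimated correlation). The call was also lost with the filter on dim probe sets (adjusted p = 0.114), which left 5 members and moved the median from 0.39 to 0.78. In the other 9 splits of the arrays, camera at its preset correlation called the expansin list in 1 and the OTP and CRR list in 2.

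Plastid-encoded transcripts changed in 24 of 69 genes, 15 higher and 9 lower, and the largest falls exceeded the largest rises in size. atpA, a subunit of the plastid ATP synthase, fell by 2.81 ± 0.15 and petG, of the cytochrome b6f complex, by 2.82 ± 0.47, from 5.48 to 2.66, a value near background. The rises were at most 0.76, in rpoC2 of the plastid RNA polymerase, followed by ycf3 at 0.67. psbI and psbK, chosen after their values were seen, fell by 1.95 and 1.33. The median was 0.10 and the mean -0.04, and camera did not call the list (adjusted p = 0.163, direction up; adjusted p = 0.853 with an estimated correlation). It did so with quantile normalization (adjusted p = 0.0474), with median centring (0.0476) and without wild type replicate 2 (0.0125). Adjusted over the list alone, 23 passed.

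**Figure D2:**
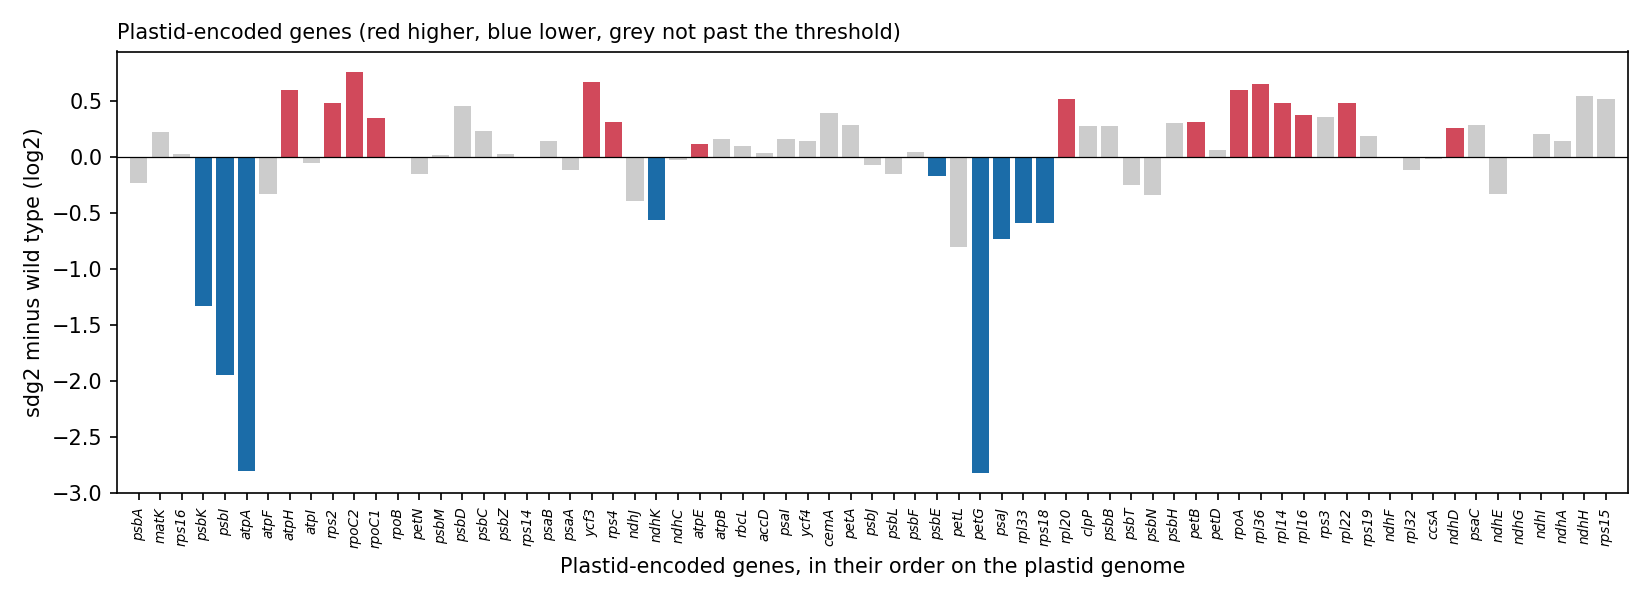
Log2 change (sdg2 minus wild type, vertical axis) of the 69 plastid-encoded genes measured, 1 bar per gene in the order of the plastid genome, red where higher, blue where lower and grey where the change did not pass. The 2 longest bars are the falls of petG, -2.82, and atpA, -2.81, and no rise exceeds 0.76.

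**Figure D3:**
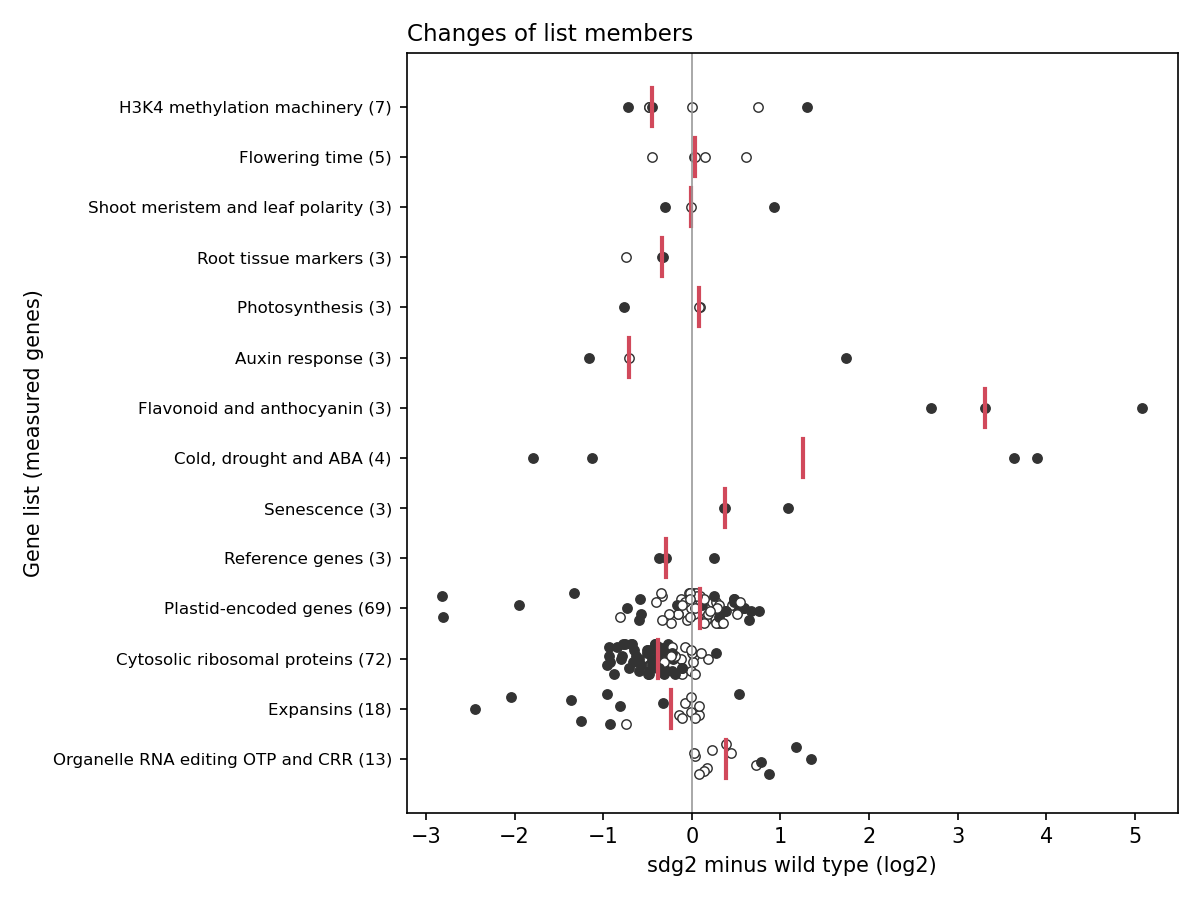
Log2 change (sdg2 minus wild type, horizontal axis) of every measured gene in the 10 fixed lists with at least 3 measured members and in 4 added lists, 1 row per list, with filled points for genes past the threshold, open points for the others and a red bar at the list median. Ribosomal protein genes centre on a median of -0.38 and the 3 flavonoid and anthocyanin genes lie at 2.70 or above.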

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

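The tests of the ribosomal and plastid patterns below were chosen only after those results were seen, while the test of RNA integrity was planned.

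The level of the GAPDH control probe sets, of which only the 3' minus 5' difference was compared above, was outside the main measurement. These probe sets gave a higher signal in sdg2, by 0.38 on the log2 scale on average, and all 5 passed in limma, also with quantile normalization (mean 0.45) and median centring (mean 0.35). The 6 actin controls had a mean change of 0.05 and the 5 ubiquitin controls of -0.10; none of them passed in limma, with 1 and 3 at an unadjusted p below 0.05. The 27 probe sets for Bacillus transcripts had a mean change of -0.24 (from -0.67 to 0.06), with 5 lower in sdg2 and 9 at an unadjusted p below 0.05. The 18 hybridization controls had a mean change of -0.19 (from -0.52 to 0.15), with 1 lower and 4 at an unadjusted p below 0.05. The 3' minus 5' signal was 0.46 ± 0.03 (SD, n = 3) in wild type and 0.49 ± 0.11 in sdg2, a difference of 0.0330 with a 95% confidence interval from -0.145 to 0.211.

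The listed cytosolic ribosomal protein genes fell together, with a median of -0.38, while AT3G28500, a P2 protein gene outside the list, rose. A slight fall of all bright probe sets is argued against, since the lowest median among 10000 random lists matched on mean expression was -0.29. A fall carried by 1 array is argued against as well, since the highest list median with 1 array left out was -0.36. An effect of the genotype, direct or through growth, was not tested and stays open.

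The changed plastid genes lie in runs along the plastid genome, with psbK, psbI and atpA in a run of falls and petG, psaJ, rpl33 and rps18 in another, members chosen after their values were seen. Neighbouring genes changed together in 9 adjacent pairs of the same direction, against a mean of 3.90 in 10000 shuffles of the calls along the gene order (permutation p = 0.0051, one-sided). All 9 fallen genes had a wild type mean of at least 5, but a gene has to start above background to be called lower. That count therefore cannot decide whether dim probe sets are the source of the falls. In sdg2 the means of psbK, psbI, atpA, psaJ, rpl33 and rps18 were still 8.59 or above, whereas petG reached 2.66, near background. Neighbouring plastid genes on the same strand are often read into shared transcripts, so changes in long plastid RNAs may lie behind a run whose genes share a strand. The strands of these genes were not compared, so it is not shown that the genes of either run share an RNA. A change in shared RNAs was not tested, and the first run of falls ended at atpA. The next gene, atpF, had a change of -0.33 that did not pass, and atpH after it rose by 0.59. A change in how much plastid RNA carries the poly(A) tails that the labelling starts from was not tested and stays open, as does a direct effect of the genotype.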

How the results depend on the processing

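The alternatives and splits for the added gene lists were chosen after the data were seen, and the others were planned. With only the 13513 probe sets naming 1 gene, 4114 changed (1959 higher, 2155 lower), 1189 of them at 2-fold or more (519 higher, 670 lower). These 1189 are all among the 2406. Fewer probe sets were tested, but those naming 1 gene were also called less often. In the fit over all probe sets 4268 of these 13513 changed, against 8327 of all 22746. Under the other alternatives 6991 (unmoderated statistics) to 9213 (array weights) changed, and 2127 (filter on dim probe sets) to 2440 (array weights) at 2-fold or more. Without any 1 array, 7368 to 7565 changed (3782 to 3905 higher, 3535 to 3685 lower), and 2349 to 2410 at 2-fold or more (1135 to 1170 higher, 1208 to 1240 lower). Higher calls were 52.0% of all, 51.1% with quantile normalization and 48.2% with median centring, so the majority direction is not settled. Limma's treat kept 2158 of the 2406. With the replicate block 7865 changed, 2363 at 2-fold or more, and 109 named genes passed, YAB3, GI, CYP71B34, XTH16 and ACT11 losing their calls; same-numbered arrays correlated at -0.008, 0.072 and 0.064 in their deviations, and not every array correlated best with its own number. Of 116 named genes 114 passed, which follows from the rule, since it took genes past the threshold wherever there were any. Without any 1 array 103 to 108 passed, and 100 passed under every alternative that gave a value. None of the 114 that passed changed direction, as is likely for genes picked by the size of their change. Camera called 2 fixed lists, also without any 1 array, but 0 with the filter on dim probe sets, which left both under 3 members, 0 with an estimated correlation (1 at an unadjusted p below 0.05) and 7 with fry. It called 3 added lists, 3 to 4 without any 1 array, but 1 with the filter and 1 with an estimated correlation, and fry called 13; the cause was not tested, though fry does not compare a list with other genes. The alternatives for the SDG2 transcript were not run. Signal over background limits what can be seen of dim transcripts, since 31.9% to 32.5% of the values on an array lay below 3. The 10 splits of the 6 arrays are too few for a share under 0.05, and each of the others mixes the genotypes unequally and so keeps part of their difference. The real split gave 8327 changed probe sets, 2406 at 2-fold or more and 2 fixed lists, each with a highest other split of 0 (225 to 990 probe sets at an unadjusted p below 0.05), and 3 added lists, with a highest other of 4; 1, 1, 1 and 2 splits were as large, the real one included.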

Other observations

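The test of hypoxia genes without members among the 300 largest changes was chosen after the result was seen, and the other tests were not. The hypoxia and sugar-starvation lists were written after some members had been seen among the largest changes, and those members were left out of the tests.

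Camera did not call the families described here, and most of them held both risen and fallen genes. In some of them 1 direction rests on calls lost with unmoderated statistics and when some single arrays were left out. These were both falls among the cytochromes P450 (CYP718 and CYP71B34) and both among the small heat shock proteins (AT1G54050 and AT2G19310). The only rise among the pollen and gametophyte genes (ACT11) was lost in the same way. In several families many members were dim, so not passing does not show that a gene was unchanged. The filter on dim probe sets kept 5 of 14 SWEET genes, 10 of 24 cytochromes P450 and 10 of 24 XTH and GH9 wall enzymes. It kept 4 of 16 genes of auxin synthesis and response and 4 of 20 pollen and gametophyte genes. Of 15 measured defensins and thionins 3 rose and 5 fell, with PDF1.2b higher by 3.56 ± 0.15 and PDF2.5 at -3.53 ± 0.20. AT1G66100, the thionin gene with the largest fall, has no family symbol and is not on this list or in its counts. PDF1.2 and PDF1.2b are close copies, and cross-reading of their probe sets was not tested. Of 14 SWEET sugar transporters 1 rose and 3 fell, with SWEET2 at -2.91 ± 0.10, SWEET16 at -1.59 ± 0.10 and SWEET1 at 0.82 ± 0.09. Of 40 AGAMOUS-like MADS-box genes 2 fell and 38 did not pass. AGL87 was at -2.74 ± 0.08 and AGL21 at -1.04 ± 0.18, from 4.05 to 3.00. The filter on dim probe sets kept only 5 of these 40 genes, so most could hardly have shown a fall. Of 11 tau glutathione transferases 3 rose and 6 fell, led by GSTU25 at 1.61 and GSTU28 at -1.44. Of 20 beta-glucosidases 4 rose and 3 fell, with BGLU28 at 2.94 ± 0.27 from a wild type mean of 2.81, near background, and BGLU45 at -1.28 ± 0.17. Of 47 UDP-glycosyltransferases 13 rose and 5 fell, with UGT78D1, a flavonol rhamnosyltransferase, at 1.65 ± 0.10. Of 24 cytochromes P450 8 rose and 2 fell, with CYP71B36 at 2.27 ± 0.10 from a wild type mean of 2.71, near background. Of 8 small heat shock proteins 4 rose and 2 fell, with AT2G29500 at 1.44.

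Of 8 autophagy ATG genes 1 rose and 3 fell, and ATG8E had a change of -1.38 ± 0.05. Of 29 serine carboxypeptidase-like genes 6 rose and 3 fell, with scpl35 at 1.49 and scpl31 at -1.77. Of 22 TBL genes of wall acetylation 3 rose and 6 fell, with TBL26 at 1.63 and TBL36 at -1.34, and of 24 XTH and GH9 wall enzymes 2 rose and 5 fell. Of these wall enzymes only 3 passed adjusted over the list alone, and 3 with unmoderated statistics. Of 33 genes of ubiquitin conjugation 8 rose and 7 fell. Of 16 genes of auxin synthesis and response 1 rose and 3 fell, of 20 pollen and gametophyte genes 1 rose and 2 fell, and of 12 RNA polymerase subunits 1 fell. Median and mean differed in sign in 5 of the 20 added lists.

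Hypoxia-response genes were weighed as a hypothesis, because 10 of 11 members seen at first had fallen, such as AT1G19530 and AT3G29970, while PDC2 rose by 2.17. Of 17 further members 8 fell, 2 rose and 7 did not pass, with a median of -0.36 (camera adjusted p = 0.0385; p = 0.0898 with an estimated correlation). AT3G03270 fell by 2.06 ± 0.11 and AT3G10020 by 1.03 ± 0.08, and AT1G72940 rose by 1.11 ± 0.12, examples chosen after their values were seen. Without AT3G03270, the 1 further member among the 300 largest changes, the median of the other 16 was -0.29 and the call was lost (camera adjusted p = 0.0894; p = 0.143 with an estimated correlation). Lower expression of genes that low oxygen induces may be part of the sdg2 difference, but the call rests on that gene, PDC2 and AT1G72940 rose, and the hypothesis stays open. Genes of the response to sugar starvation were tested in the same way, after all 5 members seen at first had fallen. Of 3 further members 2 fell, AT3G15450 by 1.58 ± 0.13 and MCCB by 1.04 ± 0.05. Their median was -1.04 (camera adjusted p = 0.0385, or p = 0.0782 with an estimated correlation). These 3 are too few genes to speak for the response.

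Adjacent genes on a chromosome that both changed 2-fold or more did so in the same direction in 38 pairs, 1.39 times the mean of 10000 shuffles (one-sided permutation p = 0.0244). They did so in opposite directions in 27 pairs, 1.02 times the mean. Without probe sets marked as reading several similar sequences the same-direction ratio was 1.33 (one-sided permutation p = 0.0537). That restriction left 5759 of 5818 measured adjacent pairs. Similar genes lying side by side were not set apart, so their share in the excess is not known. Of the 100 named genes around SDG2, 33% changed, against a median of 33% and a 95th percentile of 43% over windows of that size.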
